A study of Schizosaccharomyces pombe with 6 samples.

How the data were processed

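Haploid fission yeast (Schizosaccharomyces pombe) cells of 2 genotypes were compared by RNA-seq, with 3 libraries of wt cells and 3 of cells carrying the sad1.2 allele together with a deletion of csi1. Per the labels' protocols, each library started from 5 µg of total RNA that went through oligo-dT selection, and sequencing was paired-end. The labels call the 3 libraries of each genotype biological replicates. No DNase step is named in the protocol texts used here.

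The authors deposited raw counts per annotated transcript identifier, 1 table per library, and these counts were the input to every test. Per the submitters' processing notes, HISAT2, HTSeq and DESeq2 were used and the genome build was ASM294v2, without versions. The annotation release, the strand setting of the counting and the treatment of reads that map to several places are not given in the sources used here. Reads of a gene and its antisense partner may therefore be mixed, and values of overlapping features and of near-identical repeated copies are uncertain: 3747 of the 7269 counted features overlap a feature on the opposite strand. The authors also deposited a table of their own comparison with log2 fold changes, p-values and adjusted p-values, which was read only beside the results computed here. A further 18 columns of per-library normalized values in the deposited tables were not used.

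Gene names, feature classes, chromosomes, feature lengths and neighbourhoods came from the reference annotation of assembly ASM294v3. Since the submitters' notes name another build, no coordinates are given. Of the 7269 features, 6847 matched an annotated gene by identifier and 422 did not. Between 0.0836% and 0.0982% of each library's counts fell in unmatched identifiers, which stayed in the library totals and tests under their own identifiers. In no library did 1715 of the features have a count.

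Total counts per library ran from 19074531 to 19951875. Libraries of a genotype were compared in pairs for duplicates. The chi-square per degree of freedom over genes was 9.96 or more in every pair, so no pair agreed within sampling noise.

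The main test was the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with robust estimation, TMM normalization and genotype as the only term, on all 6 libraries. Features with too few reads were removed by filterByExpr with its defaults (minimum count 10, minimum total 15), which left 4941 genes. P-values were adjusted by the Benjamini-Hochberg method, and a gene was called at an adjusted p under 0.05. Fold changes are mutant over wt. Levels are CPM (counts over the TMM-scaled library size, as edgeR computes them), derived here from the deposited counts. Standard errors (SE) of log2 fold changes were derived from the test statistic.

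Before the data were examined, 37 gene lists were defined by name or position, of which 36 had at least 3 tested members. The remaining list, mitochondrially encoded genes, had no members because the mitochondrial identifiers in the counts did not match the reference, and it was not analysed here. A further list is not reported here. They were tested with camera of limma 3.58.1 at a preset correlation between genes of 0.01, again with an estimated correlation, and with fry. Subtelomeric and centromere-flanking genes were those within 100 kb of an end of chromosome I or II, or of a centromere. The genes named in the text follow a rule set at the same time. It takes csi1 and sad1, and up to 10 rises and 10 falls of largest size among called genes with a mean of at least 5 CPM and no overlap between genotypes. It also takes up to 3 called members of smallest adjusted p from each list, and ste11, mei2, mei4, rec8, bqt1, bqt2, cnp1, swi6, taz1, tlh1 and tlh2 where tested. Other genes named in the closing section were picked after their values were seen, and this is said there.

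The fit was tested on simulated data for this comparison, with counts drawn for the 4941 genes and known changes in 200. It recovered 34.3% of 67 genes changed 1.5-fold, 85.1% of 67 changed 2-fold and 98.5% of 66 changed 4-fold, and called 8 unchanged genes. The changes, as many up as down, were placed only in genes above a minimum mean count. Noise was drawn for each gene on its own, without the deviation that some real libraries share across genes. These rates may therefore not hold for the real libraries. With 3 libraries against 3, exact permutation of the labels cannot give a p under 0.1.

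Alternatives fixed beforehand were DESeq2 size factors, library size without a composition factor, no expression filter, a stricter filter of 5 CPM in 3 libraries, protein-coding genes only, replicate number as a block, each library left out in turn, DESeq2 1.42.0, limma voom, and windows of 50 kb. The other alternatives were added after the data were seen. One left out wt replicate 2 and mutant replicate 3 together, and another gave these libraries a covariate of their own. The last subtracted a background per kb from the mutant libraries. That background was the median gain over the wt mean in 144 protein-coding genes with a mean between 1 and 16 CPM per kb that overlap no other feature and are in none of the meiotic, mating, subtelomeric, Tf2 or stress lists. It was taken for each mutant library on its own and multiplied by the length of each feature that no other counted feature covers.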

Results

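Per the labels, RNA-seq was used to look for effects of centromere declustering on gene expression in growing cells; centromere positions are not in the data used here. In fission yeast interphase cells, centromeres gather beneath the spindle pole body. Sad1 is the inner nuclear membrane protein of the SUN family that sits there, and Csi1 links centromeres to it. Asynchronous haploid cultures of 30 mL were grown in rich medium at 30 °C and harvested in log phase at an optical density of 0.5. There were 3 biological replicates of wt and 3 of the sad1.2 csi1 deletion strain, called the mutant here. Total counts per library lay between 19074531 and 19951875 over 7269 features.

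The deleted gene was checked first. In wt, csi1 stood at 64.3 ± 0.834 CPM (SD, n = 3), and in the mutant at 7.60 ± 3.82 CPM (SD, n = 3). The raw counts were 1271, 1142 and 1225 in wt and 210, 204 and 63 in the mutant, so each mutant library lay below each wt library, as the labels require. The log2 fold change was −3.08 (SE 0.382, edgeR adjusted p = 0.0188). On the opposite strand, csi1 overlaps mrm2, so some remaining counts may come from that gene. The sad1 gene, which carries an allele and not a deletion in this strain, was higher in the mutant, at 153 ± 6.81 CPM against 81.8 ± 1.66 CPM (SD, n = 3 each). Its log2 fold change was 0.90 (SE 0.0728, edgeR adjusted p = 0.00639). It overlaps cdm1 on the opposite strand.

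**Figure D1:**
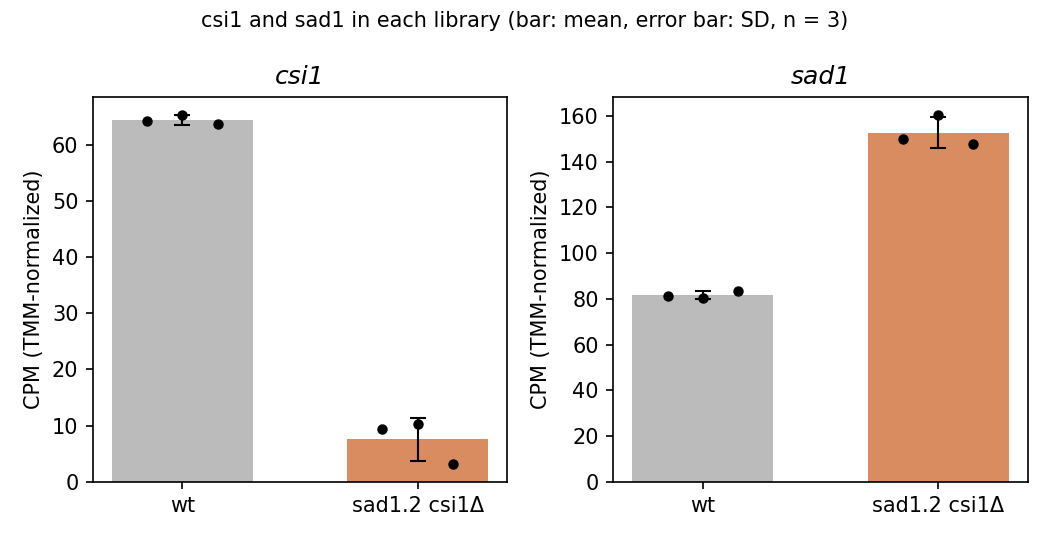
Levels of csi1 and sad1 in TMM-scaled CPM (y axis) in the wt and mutant libraries; points are libraries, bars are means and error bars are SD (n = 3). The mutant libraries lie below wt for csi1 and above wt for sad1, with means of 7.60 against 64.3 CPM and 153 against 81.8 CPM.

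Expression changed mostly upward in the mutant. Of 4941 tested genes, 113 were higher and 6 were lower at an edgeR adjusted p under 0.05, and 80 of the rises and 2 of the falls were at least 2-fold. Among the 10 largest rises at a mean of at least 5 CPM were ecl1, an extender of chronological lifespan, from 44.3 ± 1.49 to 282 ± 92.8 CPM, and the metallothionein gene zym1, from 34.1 ± 7.76 to 185 ± 61.7 CPM (SD, n = 3). Their log2 fold changes were 2.67 (SE 0.225, adjusted p = 0.00639) and 2.44 (SE 0.284, adjusted p = 0.0145). SPBC1289.14, annotated as an adducin, rose by 2.72, the uncharacterized SPBC1271.08c by 2.29 and SPCC70.04c by 2.07, and urg1, a GTP cyclohydrolase II gene, by 1.81 on the log2 scale. The non-coding RNAs SPNCRNA.1055, SPNCRNA.1382, SPNCRNA.1185 and SPNCRNA.279 rose by 1.98, 1.86, 1.72 and 1.68. Most of these calls sit near the threshold. Without wt replicate 1, wt replicate 3 or mutant replicate 2, edgeR called 0 genes (809, 678 and 932 at an unadjusted p under 0.05), and without mutant replicate 1 it called 17 higher and 0 lower. Without wt replicate 2 it called 83 higher and 5 lower, and without mutant replicate 3 it called 146 and 5. With all 6 libraries, DESeq2 called 363 higher and 152 lower and limma voom 79 higher and 3 lower.

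The 6 lower genes were csi1, the 28S ribosomal RNA feature SPRRNA.47, the cysteine transporter gene SPBPB10D8.01, the mitochondrial chaperone gene mge1, the adenine deaminase gene dea2 and hdd1. Apart from csi1, their log2 fold changes were −1.40 (SE 0.205), −0.74 (SE 0.0831), −0.41 (SE 0.0762), −0.42 (SE 0.078) and −0.37 (SE 0.0689), with edgeR adjusted p between 0.0139 and 0.0471. SPRRNA.47 belongs to a repeated gene family whose reads cannot be assigned to a copy.

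**Figure D2:**
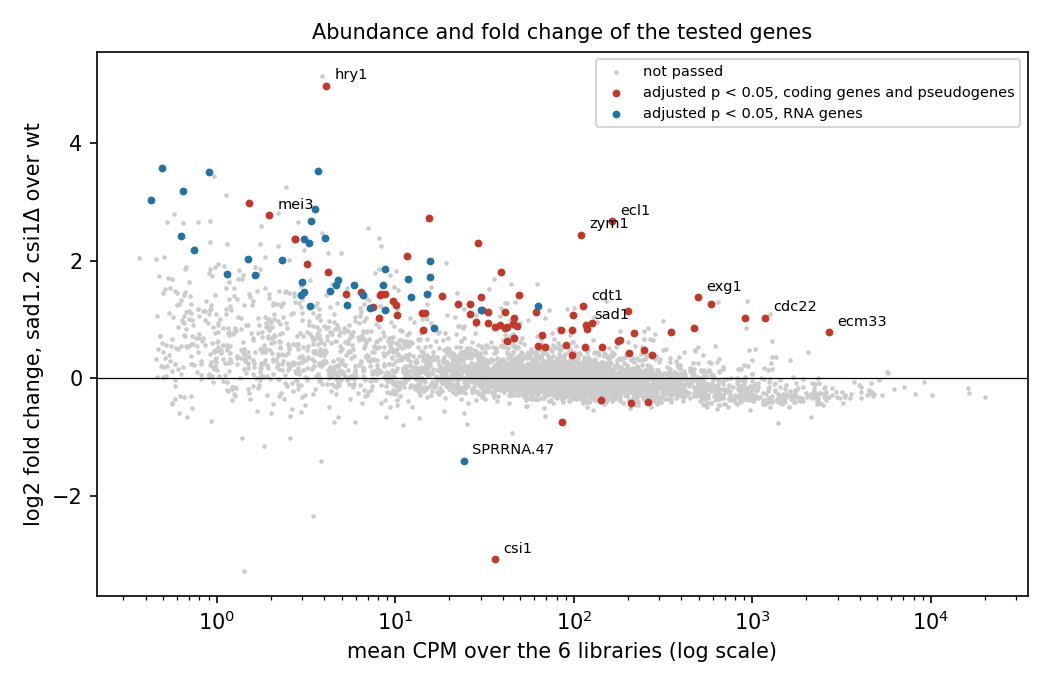
Log2 fold change of the mutant over wt (y axis) against mean CPM over the 6 libraries (x axis, log scale) for the 4941 tested genes; each point is a gene and red marks called coding genes and pseudogenes and blue called RNA genes, 113 higher and 6 lower in all. Rises among weakly expressed genes outnumber falls, and the bulk of abundant genes lies slightly below 0.

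Fold changes followed abundance. The 65 tested protein-coding genes under 1 CPM had a median log2 fold change of 0.55, the 185 genes from 8 to 16 CPM one of 0.17, the 1178 genes from 64 to 128 CPM one of −0.03 and the most abundant class one of −0.27. In 144 weakly expressed coding genes outside the meiotic, mating, subtelomeric, Tf2 and stress lists, mutant replicates 1, 2 and 3 stood 3.39, 1.60 and 1.29 CPM per kb above the wt mean, while the wt replicates lay at 0.18, −0.21 and 0.10. Of these genes 122 were higher in the mutant mean, with a median gain of 2.15 CPM per kb and quartiles of 0.722 and 3.90. When each mutant library had its own median gain (3.39, 1.60 and 1.29 CPM per kb) subtracted, edgeR called 42 genes higher and 5 lower. Of the 119 genes called without the subtraction, 43 remained. Of the 70 called genes that no longer passed, 55 kept at least 75% of their log2 fold change and 10 kept under 50%; a further 6 had too few reads left to be tested. Among the genes that no longer passed were the rises SPBC1289.14, SPBC1271.08c, SPCC70.04c, urg1 and SPNCRNA.279, at log2 fold changes of 2.66, 2.34, 1.96, 1.82 and 1.61, and 4 of the 6 lower genes, SPRRNA.47, mge1, dea2 and hdd1, at −2.47 (SE 1.01), −0.34, −0.35 and −0.30. So were isp6, frp2, gde1, map1, man1 and SPAC977.13c, at 1.22, 0.92, 0.61, 1.13, 0.57 and 1.15. The edgeR adjusted p of these 15 genes was 0.296 for SPRRNA.47 and between 0.0545 and 0.0974 for the others.

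**Figure D3:**
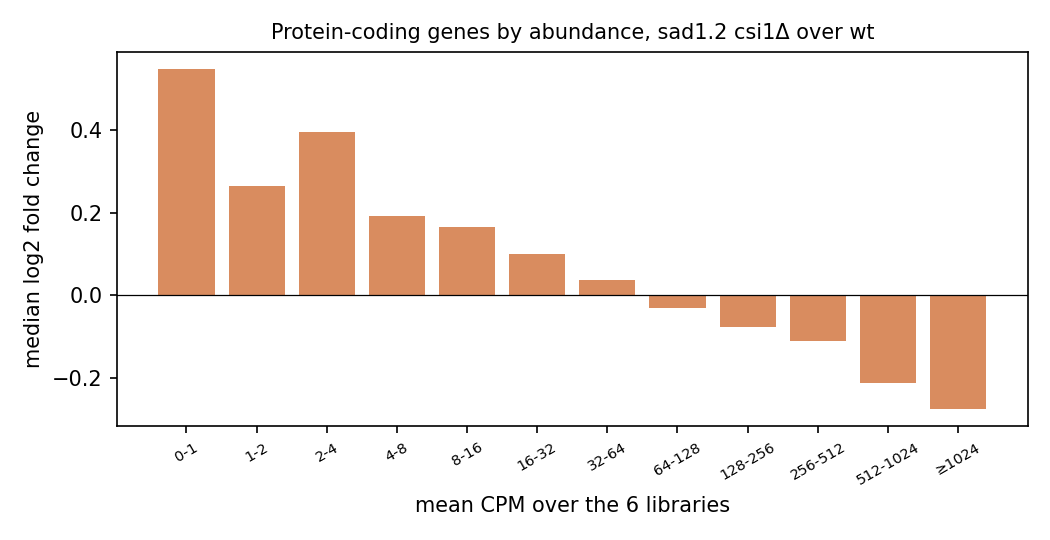
Median log2 fold change of the mutant over wt (y axis) of tested protein-coding genes in classes of mean CPM over the 6 libraries (x axis); each bar is the median of 1 class. The median is 0.55 under 1 CPM and −0.27 in the most abundant class.

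Genes of the G1/S transcription program, targets of the MBF complex that switches on at the start of the cell cycle, had rises in 6 members, while 20 had positive and 7 negative log2 fold changes. Of 27 tested members, 0 were called lower (15 were higher when adjusted over the list alone), and the median log2 fold change was 0.33. The replication licensing gene cdt1 rose from 67.3 ± 7.54 to 158 ± 8.63 CPM (SD, n = 3), with a log2 fold change of 1.23 (SE 0.104). The ribonucleotide reductase gene cdc22 rose by 1.03 (SE 0.101) and the mismatch repair gene msh6 by 0.82 (SE 0.114), with edgeR adjusted p of 0.00639, 0.0107 and 0.0234. The list passed camera (adjusted p = 1.68e-08) but not with an estimated correlation (p = 0.0124, adjusted p = 0.357). With the background subtracted the same 3 genes passed and the list median was 0.27 (over all alternatives the camera adjusted p lay between 7.51e-12 and 0.357). Among 37 spindle, checkpoint and mitosis genes, slp1, an activator of the anaphase-promoting complex, rose by 0.77 and the kinase gene fin1 by 0.53, and the list did not pass (camera adjusted p = 0.122), though it did with 4 alternatives, of which the lowest p was 0.0162 with coding genes only. Of 7 core histone genes 0 passed, with a median of −0.16 (camera adjusted p = 0.0704; 0.0215 without mutant replicate 2 and 0.046 without an expression filter), and 2 were lower when adjusted over the list alone. The DNA damage list had cdc22 as its 1 call of 31 genes (camera adjusted p = 0.290).

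Of 35 cell wall and flocculation genes, 2 were higher, both abundant. The glucan glucosidase gene exg1 rose from 275 ± 26.3 to 714 ± 147 CPM (SD, n = 3), with a log2 fold change of 1.38 (SE 0.161, edgeR adjusted p = 0.0145). The other was ecm33, which rose by 0.79 (SE 0.127). The list, with 3 higher when adjusted over the list alone and a median of −0.04, did not pass (camera adjusted p = 0.333). Outside the list, the chitinase gene cts2 rose by 1.27 (SE 0.121). After the background subtraction exg1, ecm33 and cts2 still passed.

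Meiotic genes, which are kept low in growing cells, had higher counts in the mutant. All 18 tested genes of meiotic prophase and recombination had positive log2 fold changes, with a median of 0.93. Of these, 3 passed over all genes and 12 when adjusted over the list alone. They were the kinase gene mek1 (log2 1.47, SE 0.281), the recombination gene rec10 (1.27, SE 0.218) and mug5 (1.08, SE 0.146), all 3 also members of the list of transcripts removed through the RNA-binding protein Mmi1. That list had a median of 0.99, with 3 of 12 called and 8 when adjusted over the list alone. Camera adjusted p was 1.32e-08 for the first list and 6.86e-08 for the second. With an estimated correlation neither passed (p = 0.0445 and 0.109, adjusted p = 0.357 for both). With the background subtracted, mek1, rec10 and mug5 did not pass, at log2 fold changes of 1.02 (SE 0.275), 1.15 (SE 0.225) and 0.94 (SE 0.158). The list medians were then 0.28 and 0.64, and both lists passed. Over all alternatives their adjusted p lay between 2.36e-10 and 0.357 and between 6.57e-10 and 0.357. The levels were low throughout: mek1 went from 3.41 ± 0.578 to 9.43 ± 2.99 CPM (SD, n = 3). Among the 24 genes of meiotic divisions and spore formation 0 passed over all genes and 1 when adjusted over the list alone, with a median of 0.37 (camera adjusted p = 0.0166, p = 0.239 with an estimated correlation). This list did not pass after the subtraction, without wt replicate 2 or without mutant replicate 1 (adjusted p of 0.384, 0.0728 and 0.0852, in a range from 0.00217 to 0.432 over all alternatives). The forkhead regulator gene mei4 was at 14.6 ± 6.28 against 4.98 ± 0.719 CPM (edgeR adjusted p = 0.0571) and the meiotic cohesin gene rec8 at 10.2 ± 2.97 against 5.39 ± 1.68 CPM (adjusted p = 0.155), and neither passed.

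The pheromone response and mating list had 5 of 25 genes higher and 0 lower, 8 when adjusted over the list alone, with a median of 0.34. Its leading members were the meiotic inducer gene mei3 (log2 2.77, SE 0.380), the formin gene fus1 (1.10, SE 0.151) and the M-factor precursor gene mfm1 (1.80, SE 0.299). The master regulator gene of meiosis mei2 rose from 16.8 ± 1.49 to 43.9 ± 17.1 CPM (SD, n = 3; log2 1.39, edgeR adjusted p = 0.0487), whereas ste11 was at 57.2 ± 25.5 in wt and 54.3 ± 20.1 CPM in the mutant (adjusted p = 0.935). Camera gave an adjusted p of 5.69e-06 (estimated correlation p = 0.0798, adjusted p = 0.357). After the subtraction fus1 passed while mei3, mfm1 and mei2 did not, at log2 fold changes of 0.65 (SE 0.659), 1.64 (SE 0.314) and 1.19 (SE 0.269), so mfm1 and mei2 lost their calls with most of the fold kept. The list median was 0.34 with the list still passing. Of 5 P-type mating genes, map1 rose by 1.43 (list camera adjusted p = 0.0381, p = 0.164 with an estimated correlation; 2 when adjusted over the list alone). Among other alternatives that list did not pass without wt replicate 1, wt replicate 2 or mutant replicate 1 (adjusted p of 0.0553, 0.0897 and 0.0563, in a range from 0.0108 to 0.394). Nor did the P-type list pass with replicate number as a block. The 7 M-type genes, with mfm1 called, did not pass (camera adjusted p = 0.107; 0.0422 with coding genes only and 0.047 with fry).

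Non-coding RNA genes made up 38 of the 113 rises. Of 538 tested, 38 were higher and 0 lower, or 102 higher when adjusted over the list alone, and 468 had a positive log2 fold change, with a median of 0.50. The list medians of mutant replicates 1, 2 and 3 relative to wt were 0.73, 0.47 and 0.33. Non-coding features took 0.345%, 0.345% and 0.340% of the counts in wt and 0.590%, 0.464% and 0.423% in the mutant. SPNCRNA.1600 rose from 37.7 ± 3.19 to 88.6 ± 1.86 CPM (SD, n = 3; log2 1.23, SE 0.0924, edgeR adjusted p = 0.00639). Of the 38, 19 overlap a feature on the opposite strand. The camera adjusted p was 1.04e-20, and with an estimated correlation p was 0.0708 (adjusted p = 0.357). Non-coding features that overlap nothing gained a median of 1.80 CPM per kb, against 2.15 CPM per kb in the 144 coding genes. Over all 523 non-coding features with some length of their own the median was 1.68 CPM per kb on that length, and 59.8% gained less than 2.15, so the subtraction removes somewhat more than this list gained. After the background subtraction the list median was 0.04, the list did not pass (camera adjusted p = 0.394), and 9 of the 38 calls remained, among them SPNCRNA.1600, SPNCRNA.1055, SPNCRNA.1382, SPNCRNA.1185 and SPNCRNA.1133. Of the others, 6 had too few reads left to be tested, and 18 of the 23 that no longer passed kept at least 75% of their log2 fold change.

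Genes within 100 kb of the ends of chromosomes I and II went both ways, with 79 positive and 25 negative log2 fold changes. Of these 104 subtelomeric genes, 7 were higher and 1 lower (30 and 5 when adjusted over the list alone), with a median of 0.74 (camera adjusted p = 2.3e-06, p = 0.233 with an estimated correlation). The gene hry1 rose from 0.242 ± 0.120 to 7.93 ± 4.29 CPM (SD, n = 3; log2 4.97, SE 0.646, edgeR adjusted p = 0.0231), and SPAC977.13c, a pseudogene, by 1.24. Subtelomeric genes that overlap nothing gained a median of 1.14 CPM per kb, less than the 2.15 of the 144 coding genes. With the background subtracted the list median was 0.00 and the list did not pass (camera adjusted p = 0.949), while hry1 still passed. Nor did the list pass under the stricter expression filter (0.117). All 5 tested Tf2 retrotransposons had positive values with a median of 1.34. Of them Tf2-11 passed (log2 1.42, SE 0.214), as did all 5 when adjusted over the list alone. Camera adjusted p was 3.14e-05, and p was 0.0719 with an estimated correlation. The subtraction says nothing on this list, since all 5 gained less than the 2.15 CPM per kb of the background genes (median 0.638 CPM per kb). Tf2 copies are near-identical and their counts are uncertain.

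**Figure D4:**
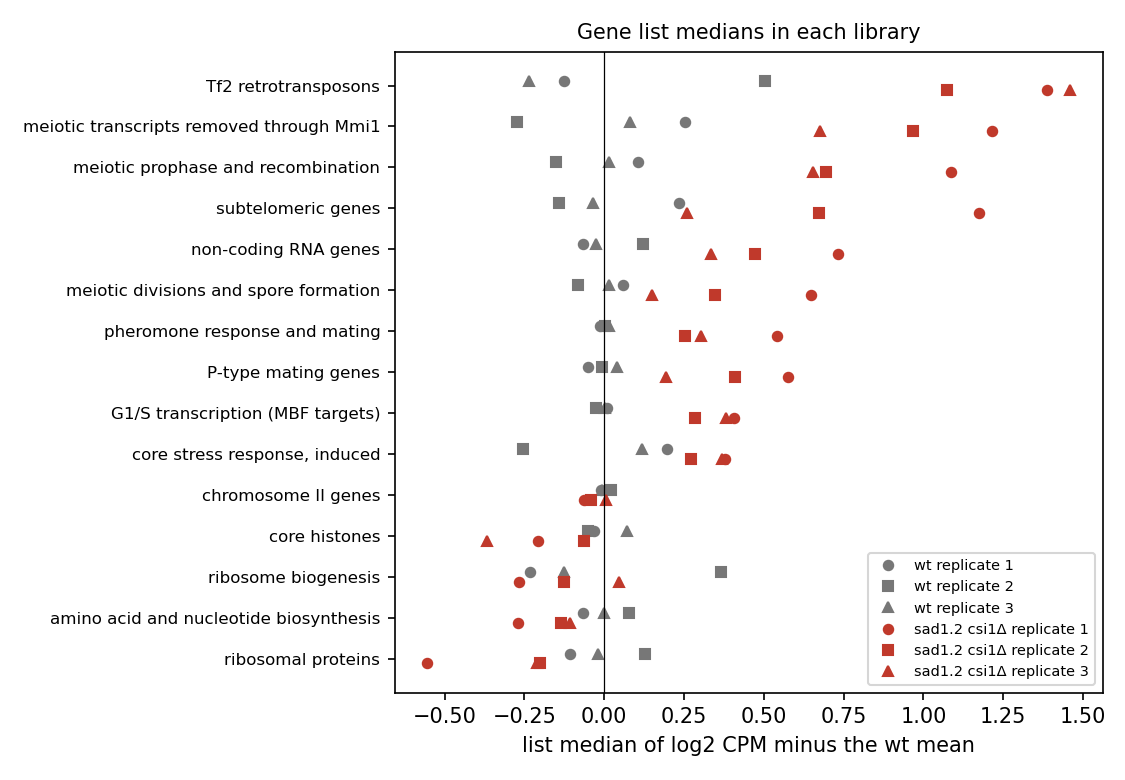
Median log2 CPM of gene lists relative to the wt mean (x axis) in each library; grey symbols are wt, red symbols are mutant, and shapes mark replicate numbers. For the non-coding RNA list the mutant libraries lie at 0.73, 0.47 and 0.33, and for ribosomal proteins at −0.56, −0.20 and −0.21.

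Stress and nutrient genes changed in part. Of 39 induced core stress genes, 3 were higher: zym1, the hexitol dehydrogenase gene tms1 (log2 0.92, SE 0.136) and the calcium pump gene cta3 (1.94, SE 0.333). The list median was 0.31, with 6 higher when adjusted over the list alone (camera adjusted p = 0.00139; estimated correlation p = 0.0779, adjusted p = 0.357). It did not pass without wt replicate 2 (camera adjusted p = 0.0728, in a range from 2.2e-05 to 0.357 over all alternatives), in which it stood at −0.25 against 0.20 and 0.12 in the other wt libraries. After the background subtraction zym1 and tms1 passed and cta3 did not, and the list median was 0.39. In the nitrogen starvation list mei2 and the vacuolar protease gene isp6 rose (log2 1.39 and 1.14), in the iron list the ferric reductase gene frp2 (1.11), and in the phosphate and thiamine list gde1 (0.68). In the glucose-repressed list the call was tms1, and mge1 fell in the heat shock list. None of these 5 lists passed camera, with adjusted p of 0.225, 0.225, 0.0974, 0.254 and 0.498. The nitrogen list passed without mutant replicate 3 (0.0124) and the glucose list without wt replicate 1 (0.00891) or mutant replicate 3 (0.0147). The phosphate and thiamine list passed with the stricter filter (0.0408), coding genes only (0.0274), the shared-axis covariate (0.0406) and the subtraction (0.0455), and the nitrogen list without wt replicate 2 and mutant replicate 3 together (0.0239).

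Translation and biosynthesis lists had negative medians, with 1 single gene called, which rose. All 111 ribosomal protein genes had negative log2 fold changes, with a median of −0.32, and in 66 of them every mutant library was below every wt library. Over all 4941 tested genes this held for 682, and in 826 every mutant library was above (chance gives 10% for both directions together). The 111 genes vary together (estimated correlation 0.544), so they are not independent results. Of the 111 genes 0 passed, also when adjusted over the list alone. The list medians per library were −0.56, −0.20 and −0.21 in the mutant and −0.11, 0.13 and −0.02 in wt. Camera gave an adjusted p of 2.86e-19, with an estimated correlation p was 0.156 (adjusted p = 0.394), and after the background subtraction the median was −0.24. Ribosome biogenesis genes, with 0 of 106 called, had a median of −0.14 (camera adjusted p = 0.000217, p = 0.506 with an estimated correlation). They did not pass without wt replicate 2 (0.701, with a median of 0.04), nor without wt replicate 2 and mutant replicate 3 together (0.264), in a range from 6.17e-09 to 0.701 over all alternatives. The 71 amino acid and nucleotide biosynthesis genes had a median of −0.17 (camera adjusted p = 3.14e-05, p = 0.217 with an estimated correlation). The 1 gene called among them, the glutamate dehydrogenase gene gdh2, rose by 1.07 (SE 0.153). Respiration genes had 0 of 51 called (camera adjusted p = 0.0557; 0.0316 without wt replicate 3, 0.0285 without mutant replicate 2, 0.0419 without an expression filter and 0.0492 with the shared-axis covariate).

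Few genes near centromeres or for nuclear architecture were called. Of 257 genes within 100 kb of a centromere, 2 were higher and 0 lower: SPAC4H3.08, a 3-hydroxyacyl-CoA dehydrogenase gene (log2 1.13, SE 0.154), and the uncharacterized SPBC27.05 (1.12, SE 0.164). The median was −0.02 and the list did not pass (camera adjusted p = 0.217). None of 37 kinetochore and centromeric chromatin genes, 25 heterochromatin and RNA interference genes or 17 telomere and bouquet genes passed, over all genes or adjusted over the list alone, with medians of 0.05, 0.11 and 0.15 and camera adjusted p of 0.713, 0.459 and 0.511. The heterochromatin and RNA interference list passed fry as higher (adjusted p = 0.047). The centromeric histone gene cnp1 was at 11.8 ± 1.32 against 10.5 ± 0.187 CPM and the telomere gene taz1 at 102 ± 9.67 against 89.1 ± 6.57 CPM (SD, n = 3). The heterochromatin gene swi6 was at 156 ± 8.59 against 165 ± 5.27 CPM. The bouquet genes bqt1 and bqt2, which tether telomeres to the spindle pole body in meiosis, were at 4.54 ± 1.25 against 3.42 ± 1.12 CPM and at 2.83 ± 0.790 against 1.69 ± 0.138 CPM. The edgeR adjusted p of these 5 genes lay between 0.172 and 0.586. The subtelomeric helicase gene tlh2 was at 1.12 ± 0.341 against 5.78 ± 5.29 CPM (adjusted p = 0.149), and tlh1, with 46 counts in all, was too low to test. In the list of 30 nuclear envelope and spindle pole body genes, sad1 rose and csi1 fell, and the LEM-domain gene man1 rose by 0.56 (SE 0.101; list camera adjusted p = 0.850).

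With fry, the Mmi1, subtelomeric, core stress, meiotic division, P-type, ribosomal protein, biosynthesis and ribosome biogenesis lists did not pass, at adjusted p between 0.0551 and 0.499. By chromosome, 59 genes were higher and 0 lower on I, 39 and 4 on II, and 14 and 2 on III. The chromosome II list passed camera as lower (adjusted p = 0.0415, p = 0.0724 with an estimated correlation) with a median of −0.04 but a mean of 0.06. It did not pass without wt replicate 1, wt replicate 2 or mutant replicate 1 (adjusted p of 0.0526, 0.0835 and 0.124), nor without an expression filter (0.0565) or with fry (0.778). Its median was 0.08 when only library size was used for scaling, which moved the median of all genes from 0.00 to 0.13. The lists of chromosomes I and III, the chromosome III ends, the mating-type region and the strain markers did not pass (camera adjusted p of 0.453, 0.0924, 0.497, 0.456 and 0.0725), with 0 calls in the last 2 lists. Chromosome III passed as higher with the stricter filter (0.0458) and chromosome I with fry (0.047). The strain markers passed as lower without wt replicate 1 (0.0439) or mutant replicate 2 (0.0261). SPRRNA.47, ecl1 and SPCC70.04c were the calls at the chromosome III ends.

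In a principal component analysis the first component took 55.2% of the variance and separated the genotypes, with wt at −9.11, −25.0 and −11.3 and mutant at 28.2, 15.6 and 1.71 for replicates 1, 2 and 3. The second took 31.7% and set wt replicate 2 (−15.4) and mutant replicate 3 (−17.2) apart from the other wt libraries (17.5 and 15.4) and mutant libraries (−1.37 and 1.10). Without these libraries, 716 genes were higher and 309 lower, with 118 of the 119 calls retained. A covariate for this shared axis gave 669 higher and 436 lower.

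In the authors' deposited table, 484 of 7235 features had an adjusted p under 0.05, 345 higher and 139 lower. Of the 116 genes called here that the authors' deposited table lists, 112 were also called there, all in the same direction. It called 345 genes more among the 4911 tested in both, and the fold changes had r = 0.907 across genes, which are not independent replicates. Lists with 0 genes called lower here had some there. It calls 18 of 136 ribosomal protein, 4 of 122 ribosome biogenesis, 10 of 89 biosynthesis and 2 of 9 core histone genes lower, with 0, 0, 1 and 0 higher. It also calls 2 of 45 kinetochore and 1 of 30 heterochromatin genes higher and 0 lower. For csi1 and sad1 the authors' deposited table gives log2 fold changes of −1.83 and 0.84, against −3.08 and 0.90 with edgeR here. DESeq2 here gave −3.09 for csi1, so the 2 sets of fold changes may not be on the same scale. The source of the difference was not tested.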

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

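Apart from the share of matched coding genes that were lower, the tests in this part were chosen after the results were seen. The authors' deposited table lists repeat features that the count tables used here do not hold. Of 120 long terminal repeat features with an adjusted p in the authors' deposited table, 6 are higher and 0 lower in the mutant, and of 9 features named SPTF, 1 is higher (SPTF.8, chosen after its value was seen, log2 fold change 0.57, adjusted p = 0.00892 in that table). They are given because no comparison of the report uses these features, but the share of long terminal repeats that is higher, 5.0%, is below the 6.30% among all features with an adjusted p in that table.

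The first pattern is the joint rise of weakly expressed classes: non-coding RNAs, subtelomeric genes and meiotic transcripts. A gain of reads per kb in the mutant libraries may underlie part of the first 2 classes. Subtracting the gain of other coding genes, taken per library (2.15 CPM per kb in the mutant mean), took their medians from 0.50 to 0.039 and from 0.74 to 0.0043. The amount stays open, because 59.8% of the non-coding and 64.1% of the subtelomeric genes had gained less than 2.15 CPM per kb. The observed gain also differed between levels. Coding genes without overlap gained medians of 1.00, 1.94, 2.20 and 2.37 CPM per kb in classes from 1 to 2, 2 to 4, 4 to 8 and 8 to 16 CPM per kb. From 16 to 32 and from 32 to 64 CPM per kb the medians were 1.58 and −0.65. The classes were cut on the mean over both genotypes, so a low class cannot hold a large gain. These medians therefore cannot decide whether a uniform amount was added. Of the meiotic lists, meiotic prophase went from 0.93 to 0.28 and meiotic divisions no longer passed camera (adjusted p = 0.384). The Mmi1 list kept a median of 0.64 and passed camera at the preset correlation. Whether this gain was the whole source in that list stays open. Overlapped lengths were left out of the subtraction, and only 5 of its 12 tested members overlap nothing. Those 5 gained a median of 4.22 CPM per kb, against 2.15 in the other coding genes. Genomic DNA in the mutant libraries could give a gain per kb. Of 65 coding genes matched to the non-coding list in CPM per kb, 13.8% were lower in the mutant, against 13.2% of the non-coding list. These 65 were not cleared of subtelomeric or meiotic genes, whose rise is part of the pattern, so the share cannot decide. Counts in mitochondrial identifiers, which whole-cell DNA would raise too, were 103, 87 and 98 in wt and 101, 88 and 73 in the mutant. They give no sign of such DNA, but they are few and the length of these features is not known here. Nuclear DNA and a genotype effect on transcription cannot be told apart, because the gain follows the genotype and reads outside annotated features were not analysed. The deviation shared by wt replicate 2 and mutant replicate 3 touches a single library of each genotype, so an equal shift in both would cancel between the genotypes. The non-coding median differed between these libraries and the others by 0.17 in wt and −0.27 in the mutant (mean −0.052). These differences have opposite signs, so their small mean is no evidence of its own.

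The second pattern is that shared deviation itself. Across genes, the deviations of wt replicate 2 and mutant replicate 3 from their genotype means correlated at r = 0.66. A swap of these libraries between the genotypes is argued against by csi1, which was 3.22 CPM in mutant replicate 3, the lowest of all libraries, and 65.3 CPM in wt replicate 2. Mixing is not excluded by csi1, since a small share of mutant reads in wt replicate 2 would hardly show. Mutant replicates 1 and 2 held 9.36 and 10.2 CPM of csi1, and whether these reads came from wt cells or from mrm2 was not tested. A different growth state of these cultures may be involved: ribosome biogenesis medians were higher than in the other libraries of the genotype by 0.55 in wt and 0.24 in the mutant, and glucose-repressed genes lay at −0.41 and −0.73. The stress list went along in wt (−0.41) but not in the mutant (0.04). No label gives a batch or a harvest density per culture, so a processing batch stays open.

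The real division of the 6 libraries called 119 genes, and the highest of the other 9 divisions into 3 and 3 called 0. Only 1 of the 10 divisions thus gave as many genes, and with 10 divisions the share cannot go under 0.1.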

How the results depend on the processing

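The background subtraction, the removal of wt replicate 2 with mutant replicate 3 and the shared-axis covariate were chosen after the data were seen. All 119 calls kept their sign under every other alternative in which they were tested, including each library left out. After the background subtraction 2 of the 113 calls still tested changed sign, Tf2-11 to −0.23 and SPBPB8B6.02c (chosen after its value was seen) to −1.75. They had gained 1.86 and 1.74 CPM per kb, less than the median of 2.15 in the genes that set the background. Genes higher or lower (113 and 6 in the main comparison) numbered 105 and 7 with DESeq2 size factors, 113 and 3 with library size only, 116 and 7 without a filter, 73 and 3 with the strict filter and 34 and 2 with coding genes only, where 92 and 77 of the 119 calls were tested. They numbered 363 and 152 with DESeq2, 79 and 3 with voom, 716 and 309 without wt replicate 2 and mutant replicate 3 together, 669 and 436 with the covariate, and 42 and 5 after the subtraction; the cause was not tested.

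Genes at least 2-fold higher or lower (80 and 2) came to 184 and 5 with DESeq2, 53 and 2 with voom, 45 and 2 with the strict filter, 22 and 1 with coding genes only, 83 and 3 without a filter, 292 and 4 without both libraries, 223 and 5 with the covariate, and 26 and 4 after the subtraction, where features reduced to 0 counts add falls. Leaving out 1 library gave 0 to 146 higher, 0 to 5 lower, 0 to 113 and 0 to 2 at least 2-fold, 8 to 13 lists higher, 2 to 7 lists lower, and csi1 at −3.34 to −2.72. Calls went to 0 without wt replicate 1, wt replicate 3 or mutant replicate 2, but numbered 88 without wt replicate 2 and 151 without mutant replicate 3; the cause was not tested. Lists higher and lower (11 and 4) were 0 and 0 with an estimated correlation and 9 and 0 with fry. They were 8 and 5 after the subtraction. The first principal component took 61.4% of the variance over the 500 most variable genes.

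The replicate numbers did not pair the libraries: the deviations of same-numbered libraries correlated at 0.44, −0.49 and −0.54. With replicate number as a block, edgeR called 0 genes higher and 0 lower and 0 and 0 at least 2-fold (845 at an unadjusted p under 0.05), csi1 was at −3.20, and 10 lists were higher and 4 lower. At this depth and with 3 libraries per genotype, the simulation recovered 34.3% of 1.5-fold changes, without a deviation shared across genes. Other depths were not analysed here.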

Other observations

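The genes of the first paragraph and the tests of G1/S genes were chosen after the results were seen, and the test of neighbouring genes was set before its result. They are given as single called genes and support no statement on a group. The gene sua7, encoding TFIIB, rose by 1.42 (SE 0.199, edgeR adjusted p = 0.0234), tbp1, encoding the TATA-binding protein, by 0.78 (SE 0.147, adjusted p = 0.0487) and the bromodomain gene bdf2 by 0.64 (adjusted p = 0.0145) on the log2 scale. The uracil phosphoribosyltransferase gene urg2 rose by 0.86, the uricase gene uro1 by 0.88 and the D-amino acid oxidase gene dao1 by 0.73. The gene spo12 rose by 1.13, the APC coactivator gene srw1 by 0.95 (SE 0.166) and the paxillin-like gene pxl1 by 0.55. The meiosis-specific non-coding RNA omt3 rose from 1.31 to 6.79 CPM. After the background subtraction sua7, bdf2 and spo12 still passed, with log2 fold changes of 1.45, 0.69 and 1.18. The others named here kept fold changes of the same sign at adjusted p between 0.0545 and 0.105.

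The third pattern is the rise of G1/S genes, and its tests were chosen after the result was seen. A hypothesis is that a larger share of mutant cells was in S phase, which would raise the histone genes too. The 7 core histones had a median of −0.16 with an SD of 0.214 between genes, below the 0.33 of the G1/S list, which argues against that share as the whole source. The median of 0.27 that remained after the subtraction is no separate test, since at the level of these genes the subtraction removes little. The 8 members that overlap nothing stood at a median of 78.9 CPM per kb. They gained a median of 23.2 CPM per kb, against 2.15 in the weakly expressed coding genes. For these 8 members that argues against a uniform gain per kb as the whole source. A change in MBF activity in the mutant stays open as a hypothesis and was not tested.

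A hypothesis was that called coding genes would lie next to each other more often than chance. Of 72 higher coding genes among 4352, 3 pairs were neighbours (cts2 with gde1, SPBC1289.14 with Tf2-11, and SPCC70.04c with ecl1), against a median of 1 in 10000 random draws (one-sided permutation p = 0.118). The number of pairs is too small to settle it.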
